A study of Mus musculus with 8 samples.

How the data were processed

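RRBS libraries were made from DNA of mouse ventral midbrain, taken up together with RNA from the same tissue. Per the labels, each library started from 100 ng of DNA digested with MspI and size-selected, libraries were pooled by 8, and 50-base single-end reads were run on a HiSeq 3000. FastQC 0.11.8, Trim Galore (its version is not given in the sources used here), Bismark 0.20.0 and methylKit 1.7.0 are named in the submitters' processing notes, with the builds mm10 and GRCm38, without their roles or order. For each library the authors deposited read counts per cytosine and strand, methylated and unmethylated, in all sequence contexts, together with a second table for CpG cytosines. That second deposited table gives the methylated fraction and the read count (coverage) of each CpG cytosine. The files have no header. Both tables of a library gave the same coverage at every CpG cytosine, and the fractions differed by at most 5e-07. Only cytosines with at least 1 call are listed. No replicates were pooled, and the counts were not normalised.

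Groups were taken from the sample labels, reading mC as mCherry and mG as Gadd45b, and checked against the reads over Gadd45b. The 4 groups held 2 libraries each: replicates 1 and 4 of mCherry at 14 d, 1 and 6 of Gadd45b at 14 d, 1 and 3 of mCherry at 90 d, and 1 and 4 of Gadd45b at 90 d. Genes were taken from a RefSeq table of GRCm38.p6, the same build as the files, with no strand, exons or genome sequence.

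Reads of the plus and minus strand were summed per CpG. A CpG was used with at least 10 reads in every library, and those among the most covered 0.1% of any library were left out. CpGs were summed over tiles of 1000 bases and over windows of 1000 bases on each side of a gene end, with at least 3 CpGs per region. Without strand the start of a gene is not known, so the end of each protein-coding gene with more covered CpGs stood in for its promoter. CpGs whose mean level lay within 2.5 points of 0 or 100%, and regions within 1.25 points, were not tested.

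Methylated and unmethylated counts were fitted per CpG, tile or gene end with a quasi-binomial logistic model over all 8 libraries in 4 groups (4 residual degrees of freedom). The overdispersion, from the Pearson statistic, was moderated across regions with squeezeVar of limma 3.58.1 and floored at 1, and each contrast had an F test with Benjamini-Hochberg adjustment. A region was called at adjusted p under 0.05 and a difference of at least 10 points (CpGs) or 5 points (tiles and gene ends). Comparisons over both times or both viruses had the other factor as an additive term. The estimated prior degrees of freedom were infinite in all 3 kinds of region, so the test used a single overdispersion for all regions: 17.0 for CpGs, 20.5 for tiles and 18.8 for gene ends, against medians of 14.2, 15.6 and 14.5. A region whose libraries vary more than that can therefore be called too easily. For this reason a stricter version was added that uses a region's own overdispersion where it is higher, and its counts stand beside those of the model. It kept the model's degrees of freedom. A value estimated from few libraries is thus taken as known, and its p-values can still be too small. edgeR 4.0.16 on methylated and unmethylated counts was the other alternative test.

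Level comparisons between libraries used exact two-sided permutation tests, adjusted within each comparison over the 9 sets of CpGs or the 5 contexts outside CpGs. The contexts overlap, since CHG and CHH divide the same cytosines as CA, CC and CT. The smallest p is 0.0286 for 4 against 4 and 0.333 for 2 against 2, so no permutation test of levels at a single time can pass. The 16 gene lists were fixed before the data were examined and tested with limma's camera (preset correlation 0.01) on log2 ratios of methylated to unmethylated reads with 1 read added to each. The calls of tiles inside genes, near gene ends and outside genes were compared with those tested by Fisher's exact test.

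Tiles were named by a rule fixed before the data were examined: at each time, among called tiles that overlap a protein-coding gene or lie within 1 kb of it and whose groups do not overlap, the 12 with the largest rise and the 12 with the largest fall, filled up to 5 where fewer pass. Gadd45b, Th and the 2 members of smallest p in each gene list were added. Because strand is not known, the 1 kb was counted from either gene end.

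The statistical code was tested on simulated data with 200 of the real regions changed. With the estimated overdispersion, at 14 d it called 1% of tiles changed by 20 points and 23% of those changed by 40 points (3 false calls), 20% and 56% of gene ends (9 false calls) and 0% of CpGs. With the times pooled it called 3% and 40% of tiles, 32% and 82% of gene ends and again 0% of CpGs. At 14 d 6.55% of unchanged tiles, 6.51% of unchanged gene ends and 6.14% of unchanged CpGs had an unadjusted p under 0.05. Counts of unadjusted p under 0.05 in the results are to be read against these shares. The simulation drew every region with the same overdispersion and so does not cover regions that vary more. The solver for additive models was replaced after values had been seen, because an earlier version had not converged at CpGs at 0 or 100% in whole groups.

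The libraries held 57426500 to 75297472 CpG calls. A single cytosine on chromosome 2 (98666481) took 2577537 to 3999187 reads per library, and cytosines with 10000 reads or more took 5.35 to 6.82% of calls. Unmethylated control DNA was read as methylated at 0.496 to 0.868% of CG calls and methylated control DNA at 98.0 to 98.6%. Regions named in the text had from 27 reads in the thinnest library to 32419 in the deepest. Reads carry no molecular identifiers and are not independent molecules, so counting limits understate the error.

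Alternatives fixed before the data were examined covered the coverage minimum and limit, thresholds, tile width, window, model, sex chromosomes, covariates and each library left out in turn. Chosen after the files had been seen were the sum of strands, the filter on mean level, residual degrees of freedom only from groups whose share is neither 0 nor 1, the coverage limit taken per library, gene ends in place of promoters, list tests on gene ends that pass the level filter, the stricter version with own overdispersion, the split of non-CpG cytosines by their next base, the families of tests for the adjustment of level comparisons, and the equal weighting of non-CpG cytosines. Exons, introns, CpG islands and repeats were not analysed here, since no genome or strand was used, and some results for single genes are not reported here. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.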

Results

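DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), in which CpG-rich MspI fragments are sequenced after bisulfite has turned unmethylated cytosines into uracil. The DNA came from the ventral midbrain of OF1 mice, an outbred stock, after injection of a virus encoding Gadd45b or mCherry into the substantia nigra. Gadd45b is a stress-induced protein linked to the removal of DNA methylation, and mCherry, a red fluorescent protein, was the control. The 8 libraries formed 4 groups of 2, for each virus at 14 d and at 90 d. The labels of single samples give days 14 to 17 and 90 to 93, whereas the series text gives 14 and 90 d for all. By the sample labels mCherry had days 14, 15, 90 and 91 and Gadd45b days 16, 17, 92 and 93. If these are true days, virus and day cannot be told apart within a time. Each library held 57426500 to 75297472 read calls at CpG cytosines, with a median of 26 to 31 reads per covered cytosine. In every library 531704 CpGs had at least 10 reads, and they filled 45103 tiles of 1 kb and 12344 windows around gene ends with at least 3 CpGs each. Regions whose mean level lay too near 0 or 100% to show the size asked for were not tested, which left 226713 CpGs, 35117 tiles and 7006 gene ends. The labels do not say that replicates are separate animals, so the spread between these libraries may be partly technical. Permutation tests of levels measure a difference against that spread. The model's p-values for regions measure it against a single overdispersion for all regions, not against the spread at the region itself. Values below are methylation levels in percent of reads, as means over libraries with ± SD where it is given, and positions are on mm10. The gene table gives neither strand nor exons, so places are stated as inside a gene, within 1 kb of a gene end or outside genes. Where a level is 0, the limit that a count of 0 allows covers counting error only, because the reads carry no molecular identifiers.

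The first question was whether the libraries carried what their labels say. Gadd45b (chromosome 10, 80930091 to 80932204) received 1689 ± 855 reads per 1000000 CpG reads in the 4 libraries of the Gadd45b virus and 9.34 ± 3.27 in the 4 mCherry libraries. The ranges, 1038 to 2851 and 6.87 to 14.1, did not overlap (181-fold, exact permutation p 0.0286, the smallest that 4 against 4 allows). The lowest Gadd45b library exceeded the highest mCherry library, taken as no lower than 3 reads in the smallest library, by over 10 times at 27 of 93 CpG cytosines inside the gene and 0 of 129 in the 3000 bases on either side. Reads inside the gene were 1.19 to 1.59% methylated in the Gadd45b libraries. The gene's own end window (18 CpGs) was at 2.01% with mCherry and 0.0466% with Gadd45b at 14 d, and at 1.38% and 1.0% at 90 d. These 18 CpGs held only 618 to 1518 reads per library in all. Each cytosine with raised reads in that window took at least 36.1 reads per 1000000 in every Gadd45b library, which alone is more than that. The raised cytosines were thus not among the 18 CpGs, whose levels hold few if any reads of the virus. Th, which encodes the rate-limiting enzyme of dopamine synthesis, had no gene end with 3 covered CpGs.

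**Figure D1:**
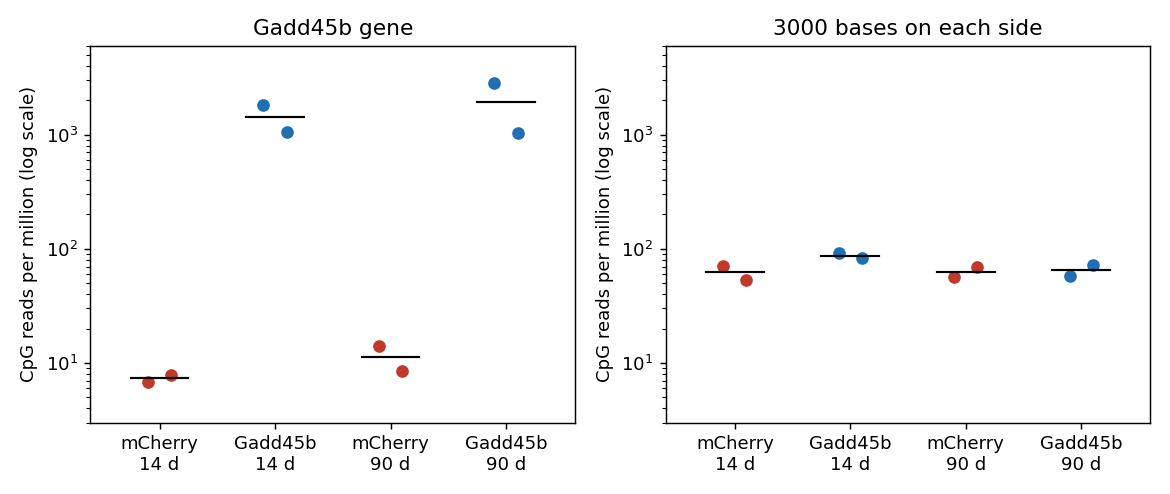
Reads over Gadd45b and over 3000 bases on each side, per 1000000 CpG reads, in each of the 8 libraries, on a log axis, by virus and time. The Gadd45b libraries lie between 1038 and 2851 and the mCherry libraries between 6.87 and 14.1.

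The mean level over all shared CpGs was compared next, to ask whether Gadd45b moved methylation as a whole. At 14 d it was 24.5 ± 1.53% with mCherry and 23.4 ± 0.215% with Gadd45b (n = 2 each). At 90 d it was 24.6 ± 0.218% and 24.1 ± 0.486%. Over both times the Gadd45b libraries were at 23.8 ± 0.498% and the mCherry libraries at 24.6 ± 0.892% (n = 4), a difference of -0.764 points that did not exceed the spread (exact permutation p 0.229). CpGs within 1 kb of a gene end were at 4.19% with Gadd45b and 4.39% with mCherry (exact p 0.2), gene bodies at 36.0% and 37.3% (exact p 0.2) and sequence outside genes at 57.3% and 58.6% (exact p 0.257). Between times the mean level differed by 0.394 points (90 d minus 14 d, exact p 0.457). CpGs with a mean above 80% were at 93.7 ± 0.168% at 90 d and 93.0 ± 0.462% at 14 d (n = 4, exact p 0.0286, adjusted p 0.257 over 9 sets of CpGs). With a minimum of 20 reads or with CpGs weighted by reads this difference, 0.742 and 0.728 points, had an exact p of 0.0571. The library mCherry 14 d replicate 4 had the highest mean, 25.6%, against 23.3 to 24.8% in the other 7. Without it the virus difference at 14 d was 0.0306 points, and without replicate 1 of that group it was -2.13. Weighted by reads the virus difference was -3.11 points at 14 d and -2.29 at 90 d, and a permutation test of 2 against 2 allows no p under 0.333.

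**Figure D2:**
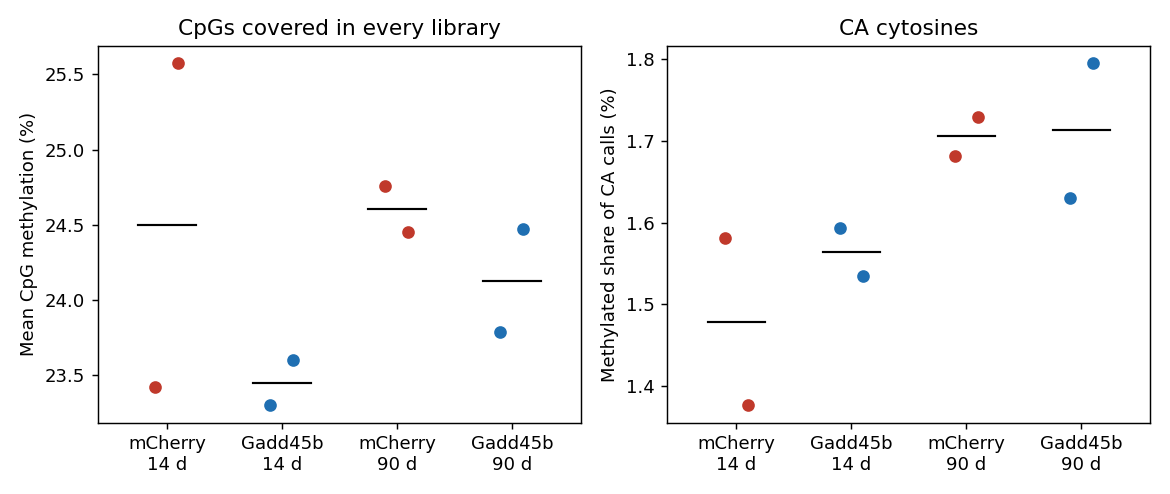
Mean CpG methylation over all shared CpGs, and the CA methylation level, in each of the 8 libraries, in percent, with bars at group means. mCherry 14 d replicate 4 has the highest CpG level, 25.6%.

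At 14 d 72 of the 92 tiles that differed had lower methylation with Gadd45b, but only 13 of 29 without mCherry 14 d replicate 4. Inside Zfpm1, which encodes a cofactor of GATA factors, the level was 71.3 ± 15.1% with mCherry and 4.32 ± 6.10% with Gadd45b (chromosome 8, 122335000 to 122335999, 7 CpGs, n = 2 each). Inside Ntrk2, the gene of the BDNF receptor TrkB, it fell from 58.6 ± 25.4% to 15.9 ± 0.259% (chromosome 13, 58810000, 4 CpGs). Inside Map3k5, which encodes the stress-activated kinase ASK1, it fell from 75.8 ± 21.7% to 25.9 ± 1.03% (chromosome 10, 19987000, 5 CpGs). At Nap1l5, an imprinted gene within Herc3, it fell from 67.7 ± 3.77% to 21.7 ± 1.40% (chromosome 6, 58906000, 9 CpGs). Near Mtch2, whose product sits in the outer mitochondrial membrane, it rose from 0.535 ± 0.669% to 11.6 ± 4.63% (chromosome 2, 90847000, 23 CpGs).

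Other falls lay inside Arhgap27, from 86.6 ± 2.05% to 25.5 ± 22.5% (chromosome 11, 103333000), and Prox1, a homeobox gene, from 85.2 ± 20.9% to 25.9 ± 11.6% (chromosome 1, 190156000). Near Vps37b, which encodes a subunit of ESCRT-I, the level fell from 87.5 ± 17.7% to 17.9 ± 25.4% over only 48 to 248 reads per library. In the sequence shared by Cmss1 and Filip1l it was 84.2 ± 9.30% and 29.0 ± 41.1% (chromosome 16, 57391000, 10 CpGs). Inside Arid1b, which encodes a subunit of the BAF chromatin remodelling complex, it was 48.2 ± 38.1% and 6.71 ± 0.926%. Cachd1 fell from 82.3 ± 14.4% to 34.0 ± 6.62% and Cracd from 86.3 ± 13.6% to 45.0 ± 28.7%. Prcd was at 48.7 ± 49.0% with mCherry and 5.66 ± 6.89% with Gadd45b. Its mCherry level was 14.1% in replicate 1 and 83.3% in replicate 4, so most of that fall came from replicate 4. Prcd was not alone: mCherry replicates 1 and 4 were at 21.3 and 75.1% at Arid1b and at 40.6 and 76.6% at Ntrk2. At other tiles they were close, such as 88.0 and 85.1% at Arhgap27. The largest rise among named tiles was inside Papss2, a gene of sulfate activation, from 36.9 ± 14.4% to 93.5 ± 3.95% (chromosome 19, 32637000, 5 CpGs). Mid1, which encodes a ubiquitin ligase bound to microtubules, rose from 19.5 ± 1.36% to 68.1 ± 16.0% (chromosome X, 169979000, 4 CpGs). The 3' part of Mid1 is shared by X and Y in the mouse, so its reads can come from either chromosome. Xylt2 rose from 58.4 ± 2.12% to 97.6 ± 3.43%, and Ntng2, the gene of netrin-G2, from 2.31 ± 3.12% to 13.9 ± 0.417%. Hepacam, a glial adhesion gene, rose from 7.57 ± 7.49% to 31.7 ± 15.9%. Fgr, a Src-family kinase gene, rose from 35.5 ± 25.8% to 64.6 ± 8.22%, and Olfr1419 from 4.59 ± 3.61% to 46.8 ± 30.2%. Tmem273 rose from 48.9 ± 22.4% to 93.4 ± 8.39% and Heg1 from 42.8 ± 34.2% to 82.3 ± 10.9%. Much of the rises at Heg1 and Fgr came from mCherry replicate 4, at 18.6 and 17.25%. Replicate 1 was at 67.0 and 53.7%, near the lower Gadd45b library (74.6 and 58.8%).

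The quasi-binomial model with limma's moderation called 92 of 35117 tiles at 14 d, 20 higher and 72 lower with Gadd45b, and 2353 had an unadjusted p under 0.05. In the simulation 6.55% of unchanged tiles had such a p, so 2353 is close to what no difference would give. Adjusted p values of the named tiles ran from 7.61e-16 at Cmss1 and Filip1l and 2.70e-10 at Mid1 to 0.0442 at Ntrk2. The 2 groups did not overlap in 68 of the 92 tiles (73.9%), against 29.7% of all tested tiles, where chance alone gives 33.3%. The 2 other splits of the same 4 libraries called 144 and 66 tiles, so a wrong grouping called more than the real one. In those tiles the share without overlap was 91.0 and 66.7%, so neither the count nor the share says much for the virus. In 60 of the 72 lower tiles mCherry 14 d replicate 4 was the highest of all 8 libraries. The count was 29 without that library (16 higher, 13 lower), 605 without replicate 1 of the same group (55 higher, 550 lower), 40 without Gadd45b 14 d replicate 1 and 38 without replicate 6. Where each tile kept its own overdispersion if that was the higher, 0 tiles were called (1419 with unadjusted p under 0.05), and edgeR called 0 (1022).

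**Figure D3:**
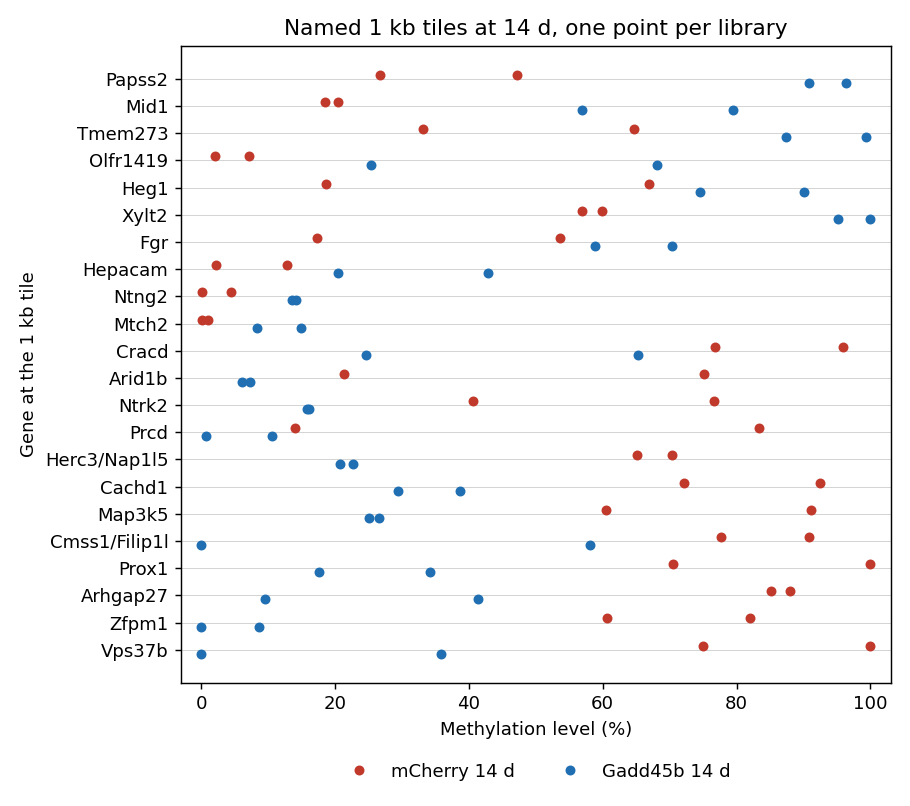
Methylation in percent of the named tiles at 14 d in each library of the mCherry and Gadd45b groups, one point per library, ordered by the difference. The tile inside Papss2 has the largest rise and the tile near Vps37b the largest fall.

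Around gene ends at 14 d, Ccne2, the gene of cyclin E2, fell from 13.8 ± 2.58% to 3.84 ± 1.13% (chromosome 4, 11189433 to 11191433, 75 CpGs). Tmem267 rose from 67.4 ± 6.47% to 77.4 ± 13.5% over 77 CpGs. In the tile of 69 CpGs there the groups overlapped (63.4 and 72.3% with mCherry, 69.9 and 87.3% with Gadd45b). That tile held 8270 to 30006 reads per library, and a single overdispersion favours deep regions. The small p at Tmem267 below thus does not measure the spread between its libraries. Gp1bb, which encodes a platelet glycoprotein, fell from 14.6 ± 0.681% to 0.0423 ± 0.0598%. Akr1e1, an aldo-keto reductase gene, rose from 15.1 ± 21.3% to 71.7 ± 23.6% over only 3 CpGs, and Uchl5 and Ro60, which share their CpGs, fell from 6.97 ± 8.20% to 0.852 ± 0.968%. In all 18 gene ends were called, 4 higher and 14 lower (431 with unadjusted p under 0.05), with adjusted p 1.77e-13 at Tmem267, 1.07e-06 at Ccne2 and 0.0456 at Gp1bb. The other called gene ends were Nap1l5, Paqr6, Slc6a16, Grrp1, Henmt1, Prrt1, Irak1bp1, Gltpd2, Rapgefl1 and Gm40862, all lower, and Mtch2 and Ntng2, both higher. These gene ends were named because the test called them, outside the rule for tiles. The groups did not overlap in 12 of the 18 (66.7%, against 100 and 82.4% of the 25 and 17 called under the 2 other splits). In 9 of the 14 lower ones mCherry 14 d replicate 4 was the highest of the 8 libraries. The count was 9 without that library (5 higher, 4 lower), 16 with a minimum of 20 reads (8 higher, 8 lower), 82 without replicate 1 of that group and 7 without Gadd45b 14 d replicate 1. It was 0 with each region's own overdispersion (261 with unadjusted p under 0.05) and 0 with edgeR (201). Of single CpGs, 0 of 226713 were called at 14 d by the same model (7468 with unadjusted p under 0.05), 0 with own overdispersion (5071) and 0 by edgeR (784). The number of CpG calls was 15 without mCherry 14 d replicate 1, 8 without Gadd45b 14 d replicate 6, 2 without mCherry 14 d replicate 4 and 1 without either Gadd45b 90 d library.

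At 90 d the called regions went both ways. Inside Dock8, the gene of a guanine nucleotide exchange factor, the level fell from 80.2 ± 10.8% with mCherry to 12.8 ± 8.40% with Gadd45b (chromosome 19, 25123000 to 25123999, 5 CpGs, n = 2 each). Inside Slc9a3, a sodium-proton exchanger gene, it was 0% with mCherry and rose to 16.4 ± 1.61% (chromosome 13, 74167000, 11 CpGs, 636 to 1540 reads per library). A count of 0 of 636 reads allows a level of up to 0.472%. Near Hjurp, which encodes the chaperone of the centromeric histone CENP-A, it rose from 1.17 ± 0.556% to 16.8 ± 2.64% (chromosome 1, 88277000, 20 CpGs). Inside Shank3, the gene of a postsynaptic scaffold protein, it fell from 22.9 ± 2.42% to 6.29 ± 6.95% (chromosome 15, 89523000, 30 CpGs).

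Rsrc1 fell from 48.1 ± 8.72% to 0% (chromosome 3, 66985000, 6 CpGs), where 0 of 204 reads allow up to 1.47%. Sipa1, which encodes a GTPase-activating protein for Rap, fell from 28.1 ± 12.3% to 2.81 ± 3.73% and Rapgefl1 from 17.8 ± 9.38% to 3.67 ± 1.72%. Arhgap23 fell from 90.9 ± 4.04% to 50.6 ± 1.55%, Eva1c from 40.6 ± 6.44% to 2.17 ± 3.07% and Exoc3l2 from 47.2 ± 13.2% to 13.8 ± 1.37%. Kcnk12, a gene of a potassium channel of the K2P family, fell from 31.1 ± 24.2% to 1.61 ± 2.28%. Ccdc30 fell from 45.3 ± 32.0% to 6.86 ± 1.91%, Cpn1 from 35.5 ± 17.0% to 4.88 ± 1.11% and Mid1 from 34.2 ± 29.9% to 4.49 ± 5.19%. Rises lay inside Socs5, a gene of a suppressor of cytokine signalling, from 18.6 ± 8.95% to 47.9 ± 14.4%, and near Irak1bp1, from 0% to 26.5 ± 29.6%. At Irak1bp1 the thinnest library had 118 reads, which at a count of 0 allow up to 2.54%. Tmem267 rose from 69.5 ± 1.89% to 81.4 ± 0.884% over 69 CpGs (chromosome 13, 119488000) and from 69.8 ± 14.5% to 90.3 ± 0.0122% in the next tile. Ccdc117 rose from 2.10 to 18.2% and Tent2, the gene of a cytoplasmic poly(A) polymerase, from 0.392 ± 0.555% to 11.5 ± 15.1%.

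The same model called 30 tiles at 90 d, 10 higher and 20 lower with Gadd45b (1918 with unadjusted p under 0.05). Adjusted p was 3.45e-11 at Tmem267, 8.10e-07 at Hjurp, 0.00131 at Dock8 and Rsrc1, 0.00134 at Slc9a3 and 0.0413 at Shank3. The groups did not overlap in 27 of the 30 (90%, against 80 and 93.1% of the 15 and 29 tiles called under the 2 other splits of the 90 d libraries). The count was 10 without mCherry 90 d replicate 1 (5 higher, 5 lower) and 18 without Gadd45b 90 d replicate 4. With own overdispersion only the tiles inside Dock8 and Slc9a3 were called (adjusted p 0.00403 for both, 1235 tiles with unadjusted p under 0.05), and edgeR called 0 (1233). Both mCherry 90 d libraries were at 0% at Slc9a3 and added nothing to that tile's own overdispersion. Where a tile's own value is not above the common one, the stricter version leaves the model's test unchanged. It also takes an own value from few libraries as known, so passing it is weak support for either tile.

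**Figure D4:**
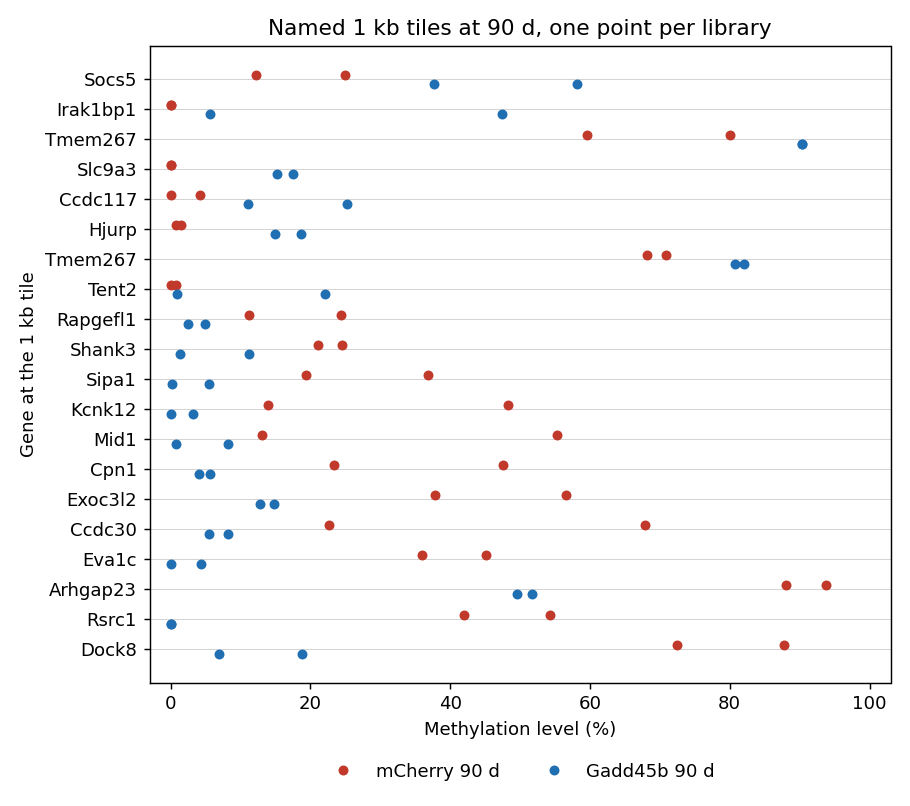
Methylation in percent of the named tiles at 90 d in each library of the mCherry and Gadd45b groups, one point per library, ordered by the difference. The tile inside Dock8 has the largest fall, from a mean of 80.2% to 12.8%.

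Of gene ends at 90 d, Irak1bp1 rose from 4.53 ± 3.50% to 28.1 ± 6.47% (chromosome 9, 82828806 to 82830806, 24 CpGs) and Edn2, which encodes endothelin-2, from 8.34 ± 5.22% to 59.0 ± 9.58% over 5 CpGs. Eng, the gene of the endothelial receptor endoglin, fell from 73.0 ± 9.99% to 35.9 ± 12.1%, and Nsmce1, a gene of the SMC5/6 complex, from 23.6 ± 3.33% to 5.97 ± 0.661%. Igf2r, an imprinted gene of a lysosomal and growth factor receptor, fell from 9.79 ± 10.1% to 2.62 ± 3.71%. With 2 libraries per group these SDs mean that the groups overlapped there. Of 22 called gene ends 9 were higher and 13 lower (433 with unadjusted p under 0.05), with adjusted p 1.13e-15 at Tmem267, 0.000280 at Irak1bp1 and 0.0480 at Edn2. The others were Hjurp, Tent2, Ccdc117, Ltb4r1, Gm8773 and Zfp995, all higher, and Mtch2, Rapgefl1, Nvl, Fkbpl, Atf6b, Ndufa13, Tssk6, Mettl23, Jmjd6 and Mfsd6l, all lower. Fkbpl and Atf6b, Ndufa13 and Tssk6, and Mettl23 and Jmjd6 are neighbours that share most of their CpGs. The groups did not overlap in 19 of the 22 (86.4%), and under the 2 other splits in 2 of 2 and 6 of 8. The count was 7 without mCherry 90 d replicate 1 (4 higher, 3 lower), 15 without Gadd45b 90 d replicate 1 (9 higher, 6 lower), 9 without Gadd45b 90 d replicate 4, 0 with own overdispersion (295 with unadjusted p under 0.05) and 0 with edgeR (282).

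Single CpGs called at 90 d were 4. A CpG inside Myd88, the gene of an adaptor of Toll-like receptors, was at 0% in both mCherry libraries and 100% in both Gadd45b libraries (chromosome 9, 119338139, 83 to 245 reads, adjusted p 3.79e-08). At 14 d the same CpG was at 58.8 ± 10.5% and 44.2 ± 62.5%. A CpG inside Nrg3, a neuregulin gene, rose from 0% to 84.6 ± 10.9% (chromosome 14, 38469037, adjusted p 0.00173). The others lay at chromosome 10, 125022089, which fell from 97.4 ± 0.262% to 67.3 ± 37.2%, and chromosome Y, 90741128, which fell from 95.3 ± 6.67% to 37.2 ± 52.6%. Without mCherry 90 d replicate 1 or replicate 3 the count was 1, and without Gadd45b 90 d replicate 1 it was 2. It was 0 with own overdispersion (4801 with unadjusted p under 0.05) and 0 with edgeR (835), against 6873 in the model itself.

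With the times pooled (n = 4 per virus, time as a covariate), 21 gene ends were called, 5 higher and 16 lower with Gadd45b. Mkrn3, an imprinted gene, fell from 37.6 ± 5.16% to 17.1 ± 3.56% (chromosome 7, 62419153 to 62421153, 14 CpGs). Nsmce1 fell from 23.7 ± 6.50% to 7.67 ± 2.47% and Bsn, the gene of the presynaptic scaffold bassoon, from 8.51 ± 2.13% to 1.64 ± 1.15%. Igf2r fell from 13.8 ± 12.2% to 3.44 ± 4.16%, Dazl, a germ cell gene, from 32.1 ± 6.26% to 18.9 ± 4.70%, and Rapgefl1 from 14.4 ± 4.30% to 4.49 ± 1.87%. At Igf2r the libraries of the 2 viruses overlapped. Ripor2 rose from 39.9 ± 17.7% to 84.4 ± 9.33% and Tmem267 from 68.2 ± 4.12% to 79.3 ± 8.10%. Adjusted p was 5.59e-06 at Tmem267, 0.00213 at Nsmce1, 0.00646 at Mkrn3 and 0.0249 at Igf2r, and 502 gene ends had an unadjusted p under 0.05. The other called gene ends were Slc6a16, Ccne2, Prrt1, Mfsd6l, Rbmxl2, Gp1bb, Paqr6, Grrp1, Nvl and Henmt1, all lower, and Zfp995, Gm8773 and Akr1e1, all higher. With own overdispersion Nsmce1 (adjusted p 0.00954) and Mkrn3 (adjusted p 0.0230) were the 2 called, and edgeR called 0 (218 with unadjusted p under 0.05). The count was 69 without mCherry 14 d replicate 1, 34 without mCherry 90 d replicate 3, 13 without mCherry 90 d replicate 1 and 11 without Gadd45b 14 d replicate 1. It was 6 with windows reaching 2000 bases outward and 500 inward, and 10 without the covariate.

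Of tiles, 0 were called with the times pooled (2253 with unadjusted p under 0.05; 1522 with own overdispersion and 1093 with edgeR, each with 0 calls). Without mCherry 14 d replicate 1 the count was 48, without mCherry 14 d replicate 4 it was 3, without mCherry 90 d replicate 1 it was 2 and without Gadd45b 14 d replicate 1 it was 1. Of single CpGs, 6 were called, 4 higher and 2 lower (12102 with unadjusted p under 0.05). The pair at chromosome 18, 59470410 and 59470419, outside genes, rose from 10.8 ± 21.5% to 99.7 ± 0.588% and from 5.22 ± 10.4% to 100% (27 to 140 reads, adjusted p 0.00166). The pair also passed with own overdispersion (adjusted p 0.00319), whereas edgeR called 0 (2385 with unadjusted p under 0.05). With all 4 Gadd45b libraries at 100% at 59470419, no own overdispersion could be estimated there. The common value was used instead, so that pass is no further support. A CpG inside Xylt2 rose from 37.7 ± 40.8% to 96.2 ± 7.53%, and a CpG at Rnaseh1 was at 0% with mCherry and 50.0 ± 57.7% with Gadd45b. The others fell, from 86.5 ± 23.3% to 55.6 ± 25.4% at chromosome 10, 125022089, and from 76.9 ± 8.01% to 45.2 ± 28.4% at chromosome 17, 39845622, which lies beside a copy of the 18S ribosomal RNA sequence, where reads of many ribosomal gene copies can fall together. Without mCherry 14 d replicate 4 the count was 2, and without mCherry 90 d replicate 3 it was 3.

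Tiles called at both times numbered 6. Tmem267 (119488000) was higher with Gadd45b at both, Shank3 and Sipa1 were lower at both, and Mid1, Mtch2 and a tile at chromosome 7, 63803000 went opposite ways. At 14 d the groups overlapped at Shank3 (3.07 and 41.9% with mCherry, 0 and 9.28% with Gadd45b), at Tmem267 (63.4 and 72.3%, against 69.9 and 87.3%) and at the tile on chromosome 7. At 90 d they overlapped at Mtch2 (32.3 and 0.0635% with mCherry, 0.867 and 0.135% with Gadd45b). Its opposite direction thus rested on mCherry 90 d replicate 1. Independent lists would give 0.00570 tiles higher at both times, 0.0410 lower at both and 0.0319 opposite, and both the 3 tiles of the same direction and the 3 of opposite direction exceeded that. Across the 116 tiles called at either time the Spearman correlation of the 2 virus differences was 0.107, and 73 (62.9%) had the same sign. Across all 35117 tiles it was 0.0471, with 51.9% of the same sign. Without mCherry 14 d replicate 4 both correlations turned negative, -0.0827 (45.6% of the same sign) and -0.00934 (49.5%). Among tiles called at either time it was also negative without mCherry 90 d replicate 1 (-0.0502) and without Gadd45b 14 d replicate 1 (-0.0317). Tiles are not independent replicates, so these values carry no p. The number called in the same direction at both times, 1 higher and 2 lower, was 1 higher and 11 lower without mCherry 14 d replicate 1 and 2 higher and 1 lower without mCherry 90 d replicate 1. It was 1 higher and 1 lower without either Gadd45b 90 d library, and 0 higher and 1 lower without Gadd45b 14 d replicate 6. No tile was lower at both times without mCherry 14 d replicate 4 (2 higher), without Gadd45b 14 d replicate 1 (1 higher) or without mCherry 90 d replicate 3 (1 higher), so Shank3 and Sipa1 each rested on these libraries.

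The virus difference itself differed between times in 33 tiles (interaction term, 1819 with unadjusted p under 0.05). At Mid1 it was 48.6 points at 14 d and -29.7 at 90 d (adjusted p 5.44e-10), and at Mtch2 11.1 and -15.7 (adjusted p 1.00e-10). The fall at Mtch2 at 90 d, from 16.2 ± 22.8% to 0.501 ± 0.518%, rested on mCherry 90 d replicate 1. That library was at 32.3% and replicate 3 at 0.0635%, against 0.867 and 0.135% with Gadd45b. At Rsrc1 the levels were 13.5 ± 19.1% with mCherry and 46.6 ± 3.14% with Gadd45b at 14 d, opposite to 90 d (adjusted p 2.95e-06). At Cracd the fall at 14 d stood against 47.6 ± 11.8% and 74.3 ± 23.4% at 90 d (adjusted p 0.00263). Of the 33, 20 had a higher virus difference at 90 d and 13 a lower one. The count was 29 without mCherry 14 d replicate 4 (11 higher, 18 lower), 120 without replicate 1 of that group, 20 without Gadd45b 14 d replicate 1, 19 without mCherry 90 d replicate 3 and 0 with own overdispersion (1156 with unadjusted p under 0.05).

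Time after injection was compared within each virus and over both. Within mCherry 39 tiles were called, 18 higher and 21 lower at 90 d. Inside Podxl, the gene of the sialomucin podocalyxin, the level rose from 5.0 ± 7.07% to 96.5 ± 3.65%, and inside Aox2, an aldehyde oxidase gene, from 15.6 ± 22.0% to 100%. Inside Bach2, a transcription factor gene, it fell from 83.8 to 0%, and inside Zfp853 it rose from 17.2 ± 3.24% to 47.2 ± 0.610%. Within Gadd45b 26 were called, 16 higher and 10 lower, among them Zdhhc14, which rose from 16.7 to 88.6%. Dlgap4, a gene of a postsynaptic density protein, fell from 71.7 to 33.0% and Mid1 from 68.1 ± 16.0% to 4.49 ± 5.19%. These tiles were chosen after their values were seen. At unadjusted p under 0.05 there were 1860 and 1797 tiles. With own overdispersion 2 were called within mCherry, at Podxl and Aox2, and 4 within Gadd45b, among them tiles at Irak1bp1, at chromosome 11, 53439000, and at chromosome 12, 3235000. Within mCherry the count was 43 without mCherry 14 d replicate 4 (32 higher, 11 lower), 233 without replicate 1 of that group, 14 without mCherry 90 d replicate 1 and 20 without mCherry 90 d replicate 3 (12 higher, 8 lower), and within Gadd45b it was 14 without Gadd45b 14 d replicate 1 and 17 without Gadd45b 90 d replicate 4.

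Over both viruses (n = 4 per time) 5 gene ends were called. Ajm1, a gene of an apical junction component, rose from 27.6 ± 6.30% at 14 d to 43.5 ± 7.16% at 90 d and Zfp995 from 10.9 ± 14.5% to 35.7 ± 21.0%. Tomm5, a gene of the mitochondrial import receptor, fell from 20.5 ± 3.21% to 6.95 ± 5.15% (adjusted p 0.0289). Gcsh, the gene of the H protein of the glycine cleavage system, fell from 16.9 ± 12.8% to 4.97 ± 3.93% and Akr1e1 from 43.4 ± 37.5% to 4.62 ± 9.24% (adjusted p 0.0269, as at Ajm1 and Zfp995). The count was 0 with own overdispersion (287 with unadjusted p under 0.05, against 421 in the model itself), 0 with edgeR (197), 0 with a minimum of 5 reads, 0 without the covariate and 1 with the other window. It was 22 without mCherry 14 d replicate 1, 12 without Gadd45b 90 d replicate 4, 10 without mCherry 14 d replicate 4 or without mCherry 90 d replicate 3, and 3 without Gadd45b 14 d replicate 1 or Gadd45b 90 d replicate 1. Of tiles 0 were called (1819 with unadjusted p under 0.05; 1268 with own overdispersion and 1020 with edgeR, each with 0 calls), but 13 were called without mCherry 14 d replicate 4, 3 without replicate 1 of that group and 1 without mCherry 90 d replicate 3.

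Single CpGs called for time numbered 8, 5 higher and 3 lower at 90 d (10937 with unadjusted p under 0.05). A CpG inside Asl, the gene of argininosuccinate lyase, rose from 25.4 ± 29.2% to 78.5 ± 29.2% (chromosome 5, 130016494), and one at Asmt, the gene of the last enzyme of melatonin synthesis, from 12.5 ± 25% to 88.4 ± 23.2% (chromosome X, 170677966). Outside genes the CpG at chromosome 12, 116175966 fell from 48.0 ± 35.1% to 0% in all 4 libraries. The remaining 5 lay at chromosome 10, 125022089, chromosome 2, 7545215, chromosome 3, 9210968, chromosome 17, 53194218 and chromosome 6, 141600566. The count was 0 without mCherry 90 d replicate 1, 2 without mCherry 90 d replicate 3 or Gadd45b 90 d replicate 4, 4 without Gadd45b 14 d replicate 6 and 5 without either mCherry 14 d library. It was 0 with own overdispersion (9646 with unadjusted p under 0.05) and 0 with edgeR (2278).

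Outside CpGs, methylation at CA cytosines, the main non-CpG form in neurons, was 1.71 ± 0.0702% at 90 d and 1.52 ± 0.0998% at 14 d (n = 4 each), a rise of 0.188 points (exact permutation p 0.0286, adjusted p 0.0357 over 5 contexts). CHG, CHH and CT levels rose by 0.0970, 0.107 and 0.0723 points (exact p 0.0286 and adjusted p 0.0357 each), and CC levels differed by 0.0191 points (exact p 0.114). CHG and CHH divide the same cytosines as CA, CC and CT, so their rises include the CA calls and are not separate results. Over cytosines with 10 reads in every library the CA rise was 0.170 points (exact p 0.0286), and the CT rise, 0.0419 points, no longer passed (exact p 0.0571). With each of these cytosines weighted equally it was 0.131 points, 1.64 ± 0.0525% against 1.51 ± 0.157%, and no longer passed (exact p 0.114), nor did CHG (0.0353 points, exact p 0.171), CHH (0.0585 points, exact p 0.114) or CT (0.0335 points, exact p 0.171). The 90 d libraries then lay at 1.57 to 1.69% for CA and the 14 d libraries at 1.29 to 1.63%, with mCherry 14 d replicate 4 lowest. Between viruses CA, CHG and CHH methylation did not differ beyond the spread (exact p 0.657, 0.971 and 0.686). The unmethylated control DNA was read as methylated at 0.496 to 0.868% of its CG calls, 0.159 to 0.568% of its CHG calls and 0.281 to 0.694% of its CHH calls. From 14 to 90 d its CHG level differed by 0.0607 points (exact p 0.657) and its CHH level by -0.183 points (exact p 0.0857).

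Gene lists fixed before the data were examined were tested on gene ends with limma's camera. None of the 15 lists with enough members passed at 14 d (lowest adjusted p 0.277), at 90 d (0.924) or pooled (0.592), and none did with an estimated correlation (lowest adjusted p 0.548, 0.973 and 0.949). Of the 14 tested genes of dopaminergic neuron identity, 7 lay above 0 and 7 below at 14 d (adjusted p 0.496) and 3 and 11 at 90 d (0.924). The dopamine transporter gene Slc6a3 was at 7.72 ± 0.00515% with mCherry and 3.77 ± 0.652% with Gadd45b at 14 d, and at 1.69 ± 0.587% and 6.04 ± 4.24% at 90 d. Slc18a2, the vesicular monoamine transporter gene, was at 3.25 ± 0.285% and 6.78 ± 3.45% at 14 d, and Pitx3, a transcription factor gene of dopamine neurons, at 9.39 ± 0.138% and 4.68 ± 1.74% at 90 d. Of 12 genes of GABA and glutamate neurons 10 lay below 0 at each time (adjusted p 0.277 and 0.924) and 11 pooled (0.592). Gad2, which encodes a GABA-synthesising enzyme, fell from 21.0 ± 7.47% to 4.11 ± 3.79% at 14 d when adjusted over the list alone (0.0357), not over all gene ends (0.274). Pooled, the NMDA receptor genes Grin2b and Grin1 differed by -7.35 and -6.65 points (0.0135 and 0.0307 adjusted over the list alone, 0.171 and 0.362 over all). Of 13 pan-neuronal and synaptic genes 8 lay above 0 at 14 d and 6 at 90 d (adjusted p 0.496 and 0.966), with Camk2a at 36.7 ± 8.76% and 0% at 90 d and Tubb3 at 1.99 ± 0.780% and 0.506 ± 0.715% at 14 d. Of 12 activity-regulated genes 6 and 4 lay above 0 (0.900 and 0.966), with Egr3 at 0.799 ± 0.137% and 2.54 ± 0.25% at 14 d and Nptx2 at 4.84 ± 1.36% and 2.32 ± 0.836% at 90 d.

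Glial and vascular lists gave no call either. Of 7 oligodendrocyte genes 6 lay below 0 at 14 d and 2 at 90 d (adjusted p 0.277 and 0.966), with Sox10, an oligodendrocyte transcription factor gene, at 7.99 ± 3.40% and 1.09 ± 1.54% and Cldn11 at 22.7 ± 15.9% and 11.5 ± 12.1% at 14 d. Of 10 astrocyte genes 7 and 5 lay below 0 (0.496 and 0.966), with Ntsr2 at 1.73 ± 1.25% and 0% and Fgfr3 at 1.90 ± 0.944% and 0.742 ± 0.0110% at 14 d. Of 4 endothelial and mural genes 3 lay below 0 at each time (0.530 and 0.966), with Flt1 at 4.48 ± 0.918% and 2.58 ± 1.40% at 14 d. The microglia list had 2 tested members, C1qa and C1qc, and no test; at 90 d C1qa was at 3.33 ± 4.71% and 21.5 ± 9.62%. Of 6 genes of the Gadd45 family and DNA methylation machinery 5 and 3 lay below 0 (0.477 and 0.924), with the methyltransferase gene Dnmt3b at 2.76 ± 1.63% and 1.29 ± 0.371% at 14 d and Gadd45g at 5.45 ± 1.66% and 0.10 ± 0.142% at 90 d. Of 4 DNA damage genes 4 and 3 lay below 0 (0.496 and 0.966), with the repair gene Xrcc1 at 8.45 ± 2.21% and 5.84 ± 0.398% at 14 d. Of 6 chromatin regulators 5 lay above 0 at 14 d and 2 at 90 d (0.277 and 0.966), with the deacetylase gene Hdac2 at 2.62 ± 0.0123% and 1.01 ± 0.00747% at 90 d.

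Of 16 imprinted genes 12 lay below 0 at 14 d and 8 at 90 d (adjusted p 0.485 and 0.966). Igf2r fell at 90 d over all gene ends, and at 14 d, from 17.8 ± 16.7% to 4.26 ± 5.97%, only when adjusted over the list alone (0.00552, against 0.0809 over all). The groups overlapped at Igf2r at both times. Over the list alone Zrsr1 fell from 48.5 ± 2.05% to 32.8 ± 5.13% at 90 d (0.00290, against 0.0908) and Cdkn1c rose by 20.4 points (0.0153, against 0.365). Peg3 was at 60.5 ± 19.9% and 32.4 ± 1.97% at 14 d. Of 36 Hox genes 25 and 20 lay below 0 (0.277 and 0.966), and Hoxa5 fell from 18.8 ± 21.1% to 6.58 ± 2.38% at 14 d when adjusted over the list alone (0.0419, against 0.151). Of 7 genes of apoptosis and MAP kinase stress signalling 5 and 3 lay below 0 (0.277 and 0.924), with Map2k4 at 2.44 ± 1.78% and 0.919 ± 0.631% at 14 d and Mapk10 at 4.40 ± 3.12% and 16.4 ± 5.52% at 90 d. Of 6 Parkinson disease genes 3 lay below 0 at each time (0.561 and 0.966). Of 28 clustered protocadherin genes, which encode neuronal adhesion proteins, 22 lay below 0 at 14 d (median -14.5 points, p 0.0246, adjusted p 0.277) and 8 at 90 d (0.924). Pcdha4 was at 64.0 ± 22.7% and 41.3 ± 6.57% and Pcdhga2 at 32.3 ± 14.2% and 17.8 ± 2.11% at 14 d. With windows of 2000 bases outward and 500 inward this list passed at 14 d (26 members, adjusted p 0.00202), but not with an estimated correlation (p 0.290), and its gene ends overlap.

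Called tiles were placed among all tiles tested. At 14 d 18.5% of called tiles lay within 1 kb of a gene end against 30.6% of tested tiles (Fisher's exact p 0.0122, adjusted p 0.0732), and 43.5% lay inside genes against 37.8%. At 90 d 43.3% lay within 1 kb of a gene end and 40% inside genes, with no adjusted p under 0.270. No place passed after adjustment at either time.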

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

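The tests of fragment choice, of conversion and of the cytosines covered at 90 d were chosen only after the result was seen, as were the fits with each region's own overdispersion, the equal weighting of cytosines, the rise per autosome without mCherry 14 d replicate 4 and the reading of imprinted gene ends against intermediate CpGs.

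The virus difference changed between 14 and 90 d in 33 tiles by the interaction term of the quasi-binomial model with limma's moderation. Virus difference at 90 d minus that at 14 d was -81.3 points at Rsrc1, -78.4 at Mid1, -48.6 at Olfr1419, -26.8 at Mtch2 and -14.1 at Ntng2. In the other direction it was 68.1 points at both Arid1b and Cracd, 49.0 at Socs5, 36.4 at Irak1bp1, 21.7 at Slc9a3 and 18.4 at Hjurp. In all these tiles the sign was opposite at the 2 times, but only Mid1 and Mtch2 were called at both. The difference at the uncalled time was small at several: -2.78 points at Hjurp and -5.29 at Slc9a3 (14 d), -2.52 at Ntng2 and -6.40 at Olfr1419 (90 d). The sign at Mtch2 at 90 d rested on mCherry 90 d replicate 1. The tile of Cmss1 and Filip1l was lower with Gadd45b at both times and changed by 12.1 points. Adjusted p ran from 1.00e-10 at Mtch2 to 0.0481 at Arid1b and at Cmss1 and Filip1l. The count was 120 without mCherry 14 d replicate 1, 20 without Gadd45b 14 d replicate 1, 19 without mCherry 90 d replicate 3 and 0 with own overdispersion.

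The mean level of the Y chromosome alone was not compared between groups. Its calls numbered 642 to 1295 per 1000000 CpG calls in the 8 libraries, above what a count of 0 allows. Cytosines with 10000 reads or more, left out of the tests by the coverage limit, held 5.35 to 6.82% of CpG calls in every library.

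The library mCherry 14 d replicate 4 stood apart, and the number of tiles called at 14 d, 92, was 29 without it and 605 without its partner. Another choice of fragments is argued against as the whole cause, since over the same CpGs in every library its mean was still 25.6% against 23.3 to 24.8%. Preferential recovery of methylated molecules remains open: imprinted gene ends were at 51.8% in it and 36.3 to 47.7% in the other 7, but with 1 parental copy methylated the highest value is also the nearest to equal shares of both copies, and at all CpGs of intermediate level it was highest too (60.1% against 46.8 to 55.5%), so this does not decide. Fewer neurons among the cells sampled also remain open: its deviation at neuronal minus glial gene ends, 0.0943 points, lay inside the range of random lists, -5.50 to 5.83, which had been set beforehand as evidence against, but that range is far wider than the excess of its mean level and so does not decide. Its CA methylation, the main non-CpG form in neurons, was the lowest of all libraries, 1.38% against 1.53 to 1.79% in the other 7. Fewer neurons would give such a difference, but this was not tested. Its sample label gives day 15 and that of its partner day 14, which was not tested, nor was any other biological explanation.

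Read shares varied between libraries far more than independent reads would, with an overdispersion of 17.0 at CpGs and 20.5 in tiles. Real differences between animals, strain variants included, are argued against as the whole cause, since the deviations of the plus and minus strand of a CpG correlated by only 0.0884 over 4103 CpGs (0.209 in mCherry 14 d replicate 4). A candidate explanation is that few source molecules were amplified into many reads, but the test did not decide. At imprinted gene ends, where both alleles should hold a like share in every animal, the SD between libraries was 0.717 of that at other CpGs of the same mean level (21.6 against 30.5 points, where counting gives 6.21), between the bounds set for either outcome. The viruses and times of the design do not bear on spread within a group, and no other biological explanation was tested.

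Methylation at CA cytosines was higher at 90 d by 0.188 points, and the exact test passed (p 0.0286) unless each shared cytosine was weighted equally (0.131 points, exact p 0.114). Incomplete conversion is argued against as the whole cause, since it would raise CC cytosines as much, and these rose by 0.0191 points over all calls (exact p 0.114) and by 0.00553 over shared cytosines (exact p 0.0286, adjusted p 0.0357), which is 10.2 and 3.25% of the CA rise against a bound set at 10%. Other cytosines covered at 90 d are argued against by a rise of 0.170 points over shared cytosines, and a few genomic regions by a rise on 19 of 19 autosomes, from 0.102 to 0.240 points (0.0551 to 0.194 without mCherry 14 d replicate 4), although on only 10 of them did every 90 d library lie above every 14 d library. A rise with age or with time after injection may account for it and stays a hypothesis, since the equal weighting ends the call and mCherry 14 d replicate 4, the lowest library, lies among the 14 d libraries. Without that library the rise over all calls was 0.139 points and with equal weights 0.0550.

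All 35 splits of the 8 libraries into 4 and 4 were refitted. For the virus over both times, 4 splits gave as many called gene ends as the real one (21, highest other 65), 14 as many CpGs (6, highest other 18) and all 35 as many tiles (0, highest other 180). For time over both viruses, 12 splits gave as many gene ends (5, highest other 27), 11 as many CpGs (8, highest other 21) and 35 as many tiles (0, highest other 19). Chance cannot be excluded for any of these counts. The split with 180 tiles and 65 gene ends set mCherry 14 d replicate 1, both Gadd45b 14 d libraries and Gadd45b 90 d replicate 1 against the rest, and so many calls point to a structure of the samples. These 4 libraries, 3 of them with Gadd45b and 3 at 14 d, had the lowest mean CpG levels, 23.3 to 23.8% against 24.5 to 25.6% in the rest. Within a time point there are only 3 splits, too few for a share under 0.05. At 14 d the real split called 92 tiles, 18 gene ends and 0 CpGs and the highest other 144, 25 and 2, and at 90 d the real split called 30, 22 and 4 and the highest other 29, 8 and 0.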

How the results depend on the processing

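The fits with own overdispersion, without the filter on mean level and with strands kept separate, the equal weighting of cytosines outside CpGs, and the libraries left out for time within a virus, for tiles called at both times and for levels outside CpGs were chosen only after the result was seen. No paired analysis was possible because within a time point the viruses share only replicate number 1. No level difference or named tile turned its direction past its threshold under the alternatives run, but the balance of calls did. Without mCherry 14 d replicate 4 the tiles went from 20 higher and 72 lower to 16 and 13 at 14 d, from 20 and 13 to 11 and 18 for the interaction, and from 18 and 21 to 32 and 11 for time within mCherry, and the gene ends at 14 d from 4 and 14 to 5 and 4. Gene ends at 90 d went from 9 higher and 13 lower to 4 and 3 without mCherry 90 d replicate 1 and to 9 and 6 without Gadd45b 90 d replicate 1. Time within mCherry was 12 and 8 without mCherry 90 d replicate 3. The few calls of single CpGs and of gene ends for time also changed their balance under several alternatives, among them 9 higher and 257 lower CpGs for the pooled virus without an upper limit on coverage. The excess of reads over Gadd45b, 181-fold, was 139-fold to 218-fold without single libraries. None of the 22 tiles named at 14 d or the 20 named at 90 d was called under every alternative. Only the tiles of Cmss1 and Filip1l and of Mid1 at 14 d, and those of Hjurp and Tmem267 (119488000) at 90 d, were called under every alternative run but edgeR and own overdispersion. Leaving out X and Y removes the Mid1 tile and says nothing about it. Other tile widths and size thresholds were not run for named tiles. These 4 tiles held 170 to 5238, 246 to 3258, 1360 to 3363 and 8270 to 30006 reads per library, against a tile median of 293. A single overdispersion for all tiles favours deep tiles, so staying called does not show that their libraries vary less. With 1 library left out, the lone library of its group is assumed to vary like the others. In simulations of the virus at 14 d and over both times no CpG changed by 40 points was called at this depth and spread, so low counts of CpGs say little about absence. For the changes given next the cause was not tested, except that a plain binomial test takes reads as independent and so calls more.

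Counts are given below for the virus at 14 d, the virus at 90 d, the virus over both times and time over both viruses, as far as they moved by over 1.5 times. The plain binomial test called 106560, 106483, 81635 and 79632 CpGs, 13834, 13368, 11019 and 10627 tiles, 1034, 1070, 758 and 686 gene ends, and 14758 tiles for the interaction. edgeR called 0 CpGs at 90 d and in both pooled comparisons, 0 tiles at 14 d and at 90 d, and 0 gene ends in all 4 comparisons. With own overdispersion the calls were 0 CpGs at 90 d, 2 for the pooled virus and 0 for time, 0 tiles at 14 d, 2 at 90 d, 2 within mCherry, 4 within Gadd45b and 0 for the interaction, and 0, 0, 2 and 0 gene ends. Without an upper limit on coverage 440, 10 and 266 CpGs were called for the virus. Without the filter on mean level the counts were 8 CpGs at 14 d, 7 at 90 d and 5 for time, 1 tile in each pooled comparison, and 31 gene ends at 14 d, 42 for the pooled virus and 17 for time. With strands kept separate 21 CpGs were called at 14 d, 2 for the pooled virus and 5 for time. A minimum of 20 reads gave 4 CpGs at 14 d, 1 tile in each pooled comparison and 13 gene ends at 90 d, and a minimum of 5 reads gave 5 CpGs and 0 gene ends for time. With only the 14 d libraries in the fit 1 CpG was called. For time, 4 CpGs passed an adjusted p of 0.01 and 4 were called without X and Y. With at least 1 CpG per region the pooled tiles were 4 for the virus and 1 for time, and with tiles of 500 bases 1 and 2. A size threshold of 10 points left 11 gene ends at 14 d. Windows of 2000 bases outward and 500 inward gave 6 gene ends for the pooled virus, 1 for time and 1 gene list at 14 d, and fits without the covariate 10 and 0 gene ends.

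The mean CpG level weighted by reads differed by -3.11 points at 14 d and -2.29 at 90 d. The rise with time at CpGs above 80%, 0.714 points, was 0.742 with a minimum of 20 reads and 0.728 weighted by reads (exact p 0.0571 for both). With shared cytosines weighted equally the rise with time was 0.131 points at CA, 0.0353 at CHG and 0.0585 at CHH, and none passed. The rise at CT was 0.0335 points in the same way and 0.0419 over shared cytosines weighted by reads, and neither passed. Over cytosines with 10 reads in every library the CHG level differed by 0.00523 points between viruses at 14 d. The Spearman correlation of virus differences between times was 0.0471 over all tiles and turned to -0.00934 without mCherry 14 d replicate 4. Over tiles called at either time it turned from 0.107 to -0.0827 without that library.

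Leaving out 1 library moved most counts, and the highest count mostly came without mCherry 14 d replicate 1. Without that library there were 15 CpGs, 605 tiles and 82 gene ends at 14 d, 4, 45 and 23 at 90 d, 48 tiles and 69 gene ends for the pooled virus, 22 gene ends for time, 233 tiles for time within mCherry, 32 within Gadd45b, 120 for the interaction and 12 called alike at both times. Without mCherry 14 d replicate 4 there were 29 tiles at 14 d, 2 CpGs for the pooled virus and 13 tiles for time, the highest for time. Without mCherry 90 d replicate 1 the lowest counts at 90 d were 1 CpG, 10 tiles and 7 gene ends, and the lowest were 0 CpGs for time and 14 tiles for time within mCherry. Without Gadd45b 14 d replicate 1 the lowest were 0 CpGs and 7 gene ends at 14 d, 11 gene ends for the pooled virus, 0 tiles and 3 gene ends for time, 14 tiles for time within Gadd45b and 1 tile called alike at both times, and the highest was 8 CpGs for time. Without Gadd45b 14 d replicate 6 there were 7 CpGs and 0 tiles for the pooled virus, and without mCherry 90 d replicate 3 there were 19 tiles for the interaction.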

Other observations

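The levels over ribosomal sequence and their tests were chosen only after the result was seen, whereas the comparison of neighbouring CpGs was fixed before the data were examined.

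At 14 d ribosomal RNA sequence carried less methylation in both Gadd45b libraries than in both mCherry libraries. Gadd45a, a relative of Gadd45b, has been linked to the removal of methylation from ribosomal genes. Over Rn18s-rs5, a copy of the 18S ribosomal RNA sequence that is annotated as a pseudogene (chromosome 17, 39846354 to 39848202, 50 CpGs), the levels were 4.79 and 14.8% with Gadd45b and 27.9 and 38.8% with mCherry. The difference of -23.6 points has an exact permutation p of 0.333, the smallest that 2 against 2 allows. At 90 d the levels were 27.5 and 20.1% with Gadd45b and 22.4 and 25.5% with mCherry, a difference of -0.132 points, and the change between times was not tested. Over both times they were 16.8 ± 9.55% and 28.6 ± 7.14% (n = 4, exact permutation p 0.0857). Over the 385 CpGs from 39843014 to 39848789, a stretch chosen because calls lay there, the 14 d levels were 3.97 and 12.2% with Gadd45b and 24.7 and 38.6% with mCherry. The highest of these values belong to mCherry 14 d replicate 4, and replicate 1 of that group also lay above both Gadd45b libraries.

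The CpGs of this stretch had a median of 3463 to 6333 reads per library. Without the upper limit on coverage 440 CpGs were called at 14 d, 13 higher and 427 lower with Gadd45b, of which 412 lay above the limit and 344 on chromosome 17 between 36231318 and 39848799. With the times pooled 266 were called, 243 above the limit and 213 on chromosome 17 between 39843014 and 39848789. An overdispersion shared across CpGs favours calls at such depth. These counts therefore add little to the differences in level between libraries. Reads of the many ribosomal gene copies can fall on the single copy in the genome build, so these levels describe the copies together.

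OF1 mice are outbred, and the CpGs called over all libraries were compared with their neighbours within 50 bases. Of 16 neighbours of the 6 CpGs called for the virus 7 (43.8%) differed in the same direction, against 38.5% beside uncalled CpGs of like coverage, and for time 18 of 32 (56.3%) against 38.1%. The called pair on chromosome 18, 59470410 and 59470419, count each other among those 7. This raises the share for the virus, which therefore shows no excess over uncalled CpGs. In all 8 libraries the level lay within 10 points of 0, 50 or 100% at 3 of the 6 CpGs (50%) called for the virus and 2 of 8 (25%) for time, against 2.83 and 2.75% of uncalled CpGs. Called CpGs were selected for large differences, which by itself favours such levels.

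Levels of single CpGs correlated between libraries by 0.724 to 0.771 over 226713 CpGs, which are not independent replicates, and the lowest value was that of the 2 mCherry 14 d libraries. The share of all CpG calls that were methylated was 29.3 and 41.2% in the mCherry libraries at 14 d, 29.6 and 32.0% in the Gadd45b libraries at 14 d, 38.6 and 36.1% in the mCherry libraries at 90 d, and 30.8 and 37.5% in the Gadd45b libraries at 90 d.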
